A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

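The samples were 2 recovery cultures of the mec1 strain WFA73, each compared on its own 2-colour array with G1 DNA of the same strain. Group membership came from the sample titles and the source names of the Cy3 channel. Per the labels' protocols, cells were arrested with alpha factor, released into 200 mM hydroxyurea for 1 h, filtered, and left to recover for 1 h with 0.8 micromolar BPS or without it. DNA ends were labelled in agarose by an end-repair reaction with Cy3 or Cy5 nucleotides, the DNA was then freed from the agarose and sonicated, per the labels' protocols. Arrays were read with Agilent Feature Extraction 9.5.1, per the submitters' processing notes.

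The deposited table gives 1 linear ratio per probe and array, which its own name calls normalized. The method of normalization, the numerator of the ratio and the genome build of the coordinates were not given in the sources used here. The medians were 1.21 without and 1.23 with BPS, so the ratio had not been centred on 1. Such a ratio states where labelled ends are enriched relative to the G1 DNA on the same array. A normalization between the dyes removes any difference in the total number of breaks, and labelling with 1 dye orientation leaves dye bias in both arrays. Dye bias that is the same on both arrays cancels in their difference. No scanner intensities were used here, so signal over background was not assessed.

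All 41480 probes were used, with no filter on low values. Ratios were converted to log2 and centred on the median of each array. Smoothed tracks are means over the probes within 2 kb either side of a probe, a median of 15 probes per window. Peaks were local maxima within 5 kb either side that exceeded the genome median of the smoothed track by 3 robust SDs (1.4826 times the median absolute deviation). None was found, so a threshold of 1 robust SD was added. A maximum counted as shared when the other array had one within 2.5 kb, and 1000 rotations of one set along the genome gave the share by chance. Adjacent probes differed with a noise SD of 0.35 without and 0.41 with BPS on the log2 scale.

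Lists of positions (origins, centromeres, chromosome ends, tRNA genes) were described by the percentile of their median among 10000 rotations along the genome, and lists of genes by the percentile among 10000 random lists of equal size, matched in 10 bins of mean signal for the difference. These percentiles describe the arrays and are not tests, because the number of arrays, 1 per group, limits the precision. Windows were 2 kb either side for origins and centromeres, 0.5 kb for tRNA genes, the outer 20 kb for chromosome ends and the reading frame or gene for gene lists. Ends with fewer than 3 probes were left out, which left 30 of 32.

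Gene names and the order of neighbouring genes came from the RefSeq table of assembly R64, which holds 6431 nuclear genes, 5799 of them with a probe. Its coordinates are not reported. Whether it lines up with the table was checked on 23 long reading frames of Ty elements, which array designs leave without probes: they held 1 probe in place, 25 probes when moved 500 bp down and 24 when moved 500 bp up the chromosome. Positions on the 7 chromosomes with such frames therefore match to within about 0.5 kb, and the other chromosomes were not checked this way. Origin positions are not part of that table. ARS416 was placed by TRP1, the origins at HML and at HMR by the mating-type genes there, and the others from general knowledge to about 0.5 kb. ARS300, ARS319 and ARS1412 could not be placed and were not analysed here. Centromeres were placed between the genes that start the left and the right arm.

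The design, the lists, the main thresholds, part of the alternatives and the rule for naming regions were set before the data were examined. Alternatives added later are named with the dependence on processing. The rule took the 10 highest peaks of each array, the 10 regions with the largest difference in each direction at least 5 kb apart, the members of the origin lists, and the highest and lowest member of each gene list by difference. Since no peak passed the threshold, the 10 highest maxima were named in their place. Other members of lists, the dip at tRNA genes, narrow features, probe-free gaps, low points, origins against their own chromosome and the left end of chromosome I were chosen after the values were seen. A list of all annotated origins and a list of Ty elements with their terminal repeats were planned and not run, the former because no origin annotation was used here and the latter because only 1 probe lay in the 23 Ty frames.

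Alternatives were windows of 1, 4 and 5 kb, other thresholds and distances, division of each array by its robust SD, no centring, quantile normalization, medians in place of means, and removal of 1605 probes near ends, 23 Ty frames and ribosomal DNA. Gene positions moved by 1 kb either way were added later. The 23 frames were picked by name and length and miss other Ty elements, so removal of 1849 probes, with those within 1 kb of any of 59 probe-free gaps over 4 kb included, was added as well. Bootstrap intervals used 2000 draws of list members and are at 95%. The procedure was tested on simulated data: of 10 planted gains of 1.5 log2 units, 10 were among the 10 largest differences, with a median error of −0.10, and a list of 30 genes shifted by 0.5 was recovered at 0.51. A list with no shift lay at the 86.05th percentile. The simulated tracks shared 1 base signal and had independent probe noise, so this checks the calculation only and not differences between cultures or arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.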

Results

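DNA double strand breaks (DSBs) were mapped across the genome of budding yeast cells lacking a working Mec1, the checkpoint kinase that protects stalled replication forks. The strain was WFA73. Cells held in G1 with the mating pheromone alpha factor were released into 200 mM hydroxyurea, which starves replication forks of deoxynucleotides, for 1 h. The drug was then filtered away and the cells recovered for 1 h in fresh medium, either without BPS or with 0.8 micromolar BPS, a chelator of iron. In the Break-chip assay the ends of broken chromosomes are labelled with a fluorescent nucleotide while the DNA lies protected in agarose, and the labelled DNA is hybridised to a tiling microarray. On each array the G1 DNA carried Cy5 and the recovery DNA carried Cy3. The question was whether the iron chelator, present during recovery, altered the genome-wide pattern of breaks.

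There was 1 array without BPS and 1 array with BPS, so no difference between them has a replicate check and no p-value was computed. Each array held a ratio for 41480 probes on 16 nuclear chromosomes, with a median of 257 bp between neighbouring probes. The median ratio was 1.21 without BPS and 1.23 with BPS, and the 1st to 99th percentiles ran from 0.426 to 3.48 and from 0.315 to 4.62. Ratios were converted to log2 and each array was set to a median of 0. A value therefore states the break signal at a place against that of G1 DNA, relative to the rest of the same genome. Each array had its own G1 channel, so a value or difference called signal here can also come from the G1 side. The total amount of breakage cannot be compared between the arrays on this scale, and extra copies of DNA replicated near origins are not separated from broken ends. The numerator of the ratio was not given in the sources used here. It was taken as recovery over G1, because the columns carry the recovery samples' names and the design sets each recovery against a G1 control. The G1 DNA carried Cy5 and the recovery DNA Cy3, so a ratio of Cy5 over Cy3 would run the other way. The values themselves did not settle the direction. If the ratio ran the other way, every sign would turn and the sites of strongest signal would be the lowest points given below. The standard error (SE) given with a region is over the probes of its window and covers scatter within the arrays only. Positions are in the kb coordinates of the deposited table, whose genome build was not given in the sources used here.

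The first comparison asked how far the landscape of breaks was shared. Broad domains of high and low signal lay in the same places on both arrays. Chromosome III, for example, had the highest median of all 16 chromosomes on both (0.40 without and 0.35 with BPS), followed by VI (0.21 and 0.23), and IV had the lowest (−0.18 and −0.15). Along chromosome III the tracks were high together around the centromere, where CEN3 had 0.87 without and 1.35 with BPS, and at ARS309 (1.05 and 1.09). Across the 41480 probes, which are neighbours on chromosomes and not independent replicates, Pearson's r was 0.766 and Spearman's rho 0.776. After averaging the probes within 2 kb either side, r was 0.865. Values spread more widely with BPS, with an SD of 0.86 against 0.72 and a slope of 1.19 between the arrays.

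**Figure D1:**
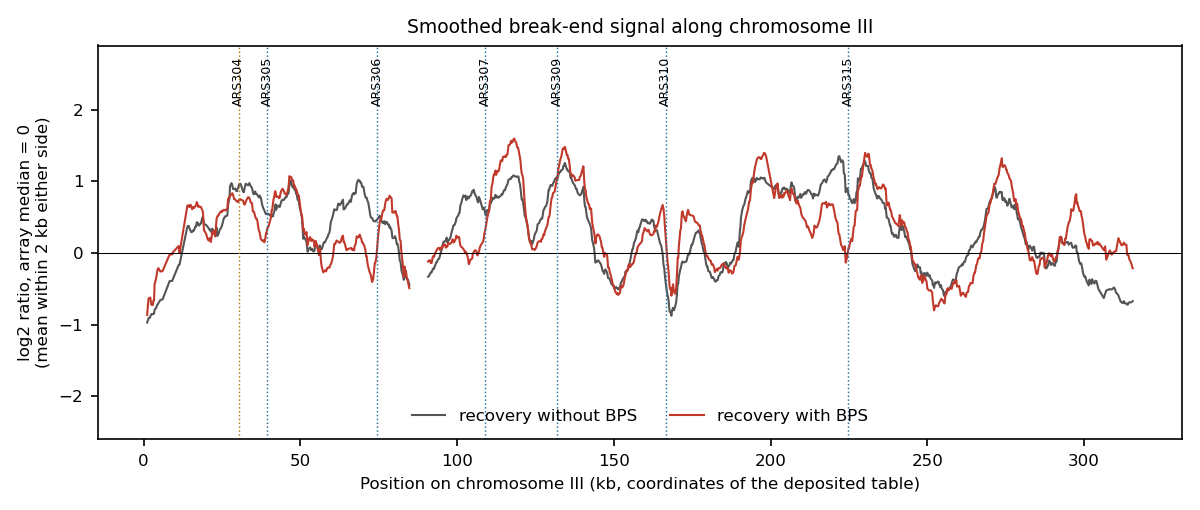
The lines show the log2 ratio (array median set to 0, mean of probes within 2 kb) against position in kb along chromosome III, in grey without BPS and in red with BPS, with dotted lines at early (blue) and late (brown) origins. The tracks follow each other at ARS309 (1.05 and 1.09), and the array with BPS is lower beside ARS315 (0.85 and 0.06).

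The 10 highest sites of each array lay at 18 separate places, 17 of them above 1 log2 unit on both arrays. Without BPS the highest site was at EKI1, an ethanolamine kinase gene (chromosome IV, 753.2 kb), at 1.66 ± 0.10 (SE, 13 probes), and it stood at 1.72 ± 0.10 with BPS. Next came a site on VII at 287.3 kb beside ARO5 (1.63 and 1.72), MLO50 on XII (245.0 kb, 1.62 and 1.76) and MIS1, which encodes a mitochondrial C1-tetrahydrofolate synthase, on II (413.4 kb, 1.59 and 1.68). FCP1, the phosphatase of the RNA polymerase II tail, followed on XIII (1.51 and 1.70), then SOA1 on IX (1.66 with BPS), RPC19 on XIV (1.26 with BPS, a difference of −0.22), ECM7 on XII (1.45 and 1.47), VPS21 on XV (1.45 and 1.18) and ATG19 on XV (1.43 and 1.94). Small differences at these 10 sites depend on scale, as the sign turned at 7 of them after quantile normalization, which makes the highest values of the arrays equal, and at 4 after division by the robust SD.

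With BPS the highest site was in NUM1 on IV (757.4 kb), at 2.07 ± 0.22 over 7 probes, against 1.32 without BPS. It lay 4.2 kb from the EKI1 site. ATG19, a receptor of selective autophagy, followed at 2.03 against 1.33. The site at SHY1 on VII (718.4 kb), a gene for assembly of cytochrome c oxidase, reached 1.92 with BPS but −0.49 without. IVY1 on IV (1.89 against 1.22), SLD7 on XV (1.87 against 1.39), ARO5 on VII (1.83 against 1.49), UBP9 on V (1.81 against 1.22), OCH1 on VII (1.81 against 1.19), CMK1 on VI (1.80 against 1.09) and MSL5 on XII (1.78 against 1.35) completed the list. SLD7 encodes a partner of the replication initiation factor Sld3. Differences at these sites depend on scale as well. After quantile normalization they were 0.40 at NUM1, 0.35 at ATG19, 0.14 at SLD7, 0.11 at MSL5 and −0.01 at ARO5, while SHY1 kept 2.26.

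The threshold for peaks set in advance, 3 robust SDs above the genome median, was met nowhere: the highest smoothed value stood 2.20 robust SDs above the median without BPS and 2.57 with BPS. At a threshold of 1 robust SD, chosen after the values were seen, there were 265 maxima without and 300 with BPS. Of the 265, 203 (76.6%) had a maximum with BPS within 2.5 kb, against a mean of 12.5% when one set was rotated along the genome, and in the other direction the share was 67.7%. At higher thresholds fewer were shared: 71.0% and 38.2% at 1.5 robust SDs, and 50% and 5.26% at 2 robust SDs, where there were 4 maxima without and 38 with BPS. The share of the maxima with BPS is capped by the shorter list without BPS, 93 against 173 at 1.5 robust SDs. Its fall therefore partly follows from the lengths of the lists. At the 274 maxima of the averaged tracks the signal was higher with BPS at 224 and lower at 50, with a median difference of 0.24 and an interquartile range of 0.07 to 0.44. The smoothed SD was 0.62 without and 0.72 with BPS, and this wider spread alone would give a positive difference at such maxima. The median difference was 0.19, in robust SDs, when each array was divided by its robust SD. The robust SDs, 0.75 and 0.81, differ less than the SDs, so this division may remove only part of the wider spread. Quantile normalization gave −0.001, but that method makes the highest values of the arrays equal, so it says little about height at maxima. None of the 265 maxima without BPS lay below the genome median on the array with BPS, while 15 of the 300 maxima with BPS (5%) lay below the median without it. The same count of 15, of 298 maxima, was found after quantile normalization.

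The low points were counted in the same way after the values were seen, since they would be the sites of strongest signal if the ratio ran the other way. There were 218 minima without and 242 with BPS at least 1 robust SD below the genome median. Of the 218, 126 (57.8%) had a minimum with BPS within 2.5 kb, against a rotated mean of 9.94%, and in the other direction the share was 52.1% against 8.99%. These shares were 38.5% and 21.7% at 1.5 robust SDs, and 10% and 6.25% at 2 robust SDs, so how far sites were shared depends on the direction of the ratio. At the 227 minima of the averaged tracks the signal was lower with BPS at 181 and higher at 46, with a median difference of −0.21. The wider spread with BPS alone would give this sign too. Of the 218 minima 10 lay above the genome median with BPS, and none of the 242 lay above it without BPS. Only 1 minimum, with BPS, reached 3 robust SDs, at −2.51 on XII (11.4 kb) over 1 probe. The lowest points without BPS were at ATG16 on XIII (574.6 kb, −1.69 and −1.14 with BPS) and at YCS4, a condensin gene, on XII (686.5 kb, −1.61 and −1.01).

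Differences between the recoveries were lopsided, with large ones mostly higher with BPS. The largest was at YGR111W on VII (714.8 to 718.8 kb), next to SHY1, where the signal was −0.80 ± 0.10 without and 1.72 ± 0.13 with BPS. That is a difference of 2.52 ± 0.09 over 16 probes, or 5.73-fold, and it spanned 8.55 kb between its points of mid-height. GSY2, a glycogen synthase gene on XII (658.7 to 662.7 kb), had −0.79 ± 0.10 without and 1.22 ± 0.15 with BPS. SEC28, a gene of the COPI vesicle coat on IX (217.2 kb), differed by 1.74 ± 0.12, in a block that extended over 22.3 kb between its points of mid-height and included a stretch from 205.2 to 210.6 kb with no probes. The region beside KTD1 on I (185.7 kb) differed by 1.73 ± 0.08, and that at RRN6, a factor for transcription of ribosomal DNA, on II (200.5 kb) by 1.69 ± 0.12.

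The list of 10 went on with YPS7 and ATP22, neighbouring maxima of a single block on IV (1173.0 and 1178.2 kb), at 1.66 ± 0.15 and 1.58 ± 0.17. GAP1, the general amino acid permease gene on XI (515.4 kb), sat in a valley of −1.23 without BPS and at 0.43 with it, a difference of 1.66 ± 0.13. GCN2, the kinase gene of the amino acid starvation response on IV (1026.1 kb), differed by 1.59 ± 0.11. The last, at SNZ3 on VI (12.1 kb, 1.53), rested on 1 probe. All of these places were below the genome median without BPS and above it with BPS.

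Losses with BPS were smaller, and 7 of the 10 lay within 20 kb of a chromosome end or rested on 1 to 3 probes. The largest were on the left arm of chromosome I, at −1.45 ± 0.29 near TDA8 (16.1 kb) and −1.34 ± 0.19 near YAL067W-A (4.4 kb). Near FLO1, a flocculin gene on the right arm of I (201.0 kb), the difference was −1.24 ± 0.24 over 18 probes. Inside the chromosomes, PWP2 on III (221.2 to 225.2 kb), a gene for processing of ribosomal RNA, had 1.28 ± 0.07 without and 0.04 ± 0.09 with BPS, a difference of −1.24 ± 0.08 that spanned 4.53 kb between its points of mid-height. AMF1 on XV (1050.6 kb) had 1.08 and 0.09, a difference of −0.99 ± 0.19. The others were at YRF1-4 (−1.31, 1 probe), YLR462W (−1.12, 3 probes) and YLL066W-B (−1.02, 1 probe) on XII, FLO5 on VIII (−1.02 ± 0.66, 2 probes) and YRF1-6 on XIV (levels of −1.15 and −2.15, 2 probes). Windows of 4 kb either side gave −0.59 at FLO1 and −0.73 at PWP2. After quantile normalization the differences were −0.54 at FLO5, −0.53 at YLL066W-B and −0.61 at YRF1-6, while PWP2 had −1.38. YRF1 genes lie in the repeated Y′ elements of telomeres, and FLO1 and FLO5 are close relatives, so probes there can share signal between copies.

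**Figure D2:**
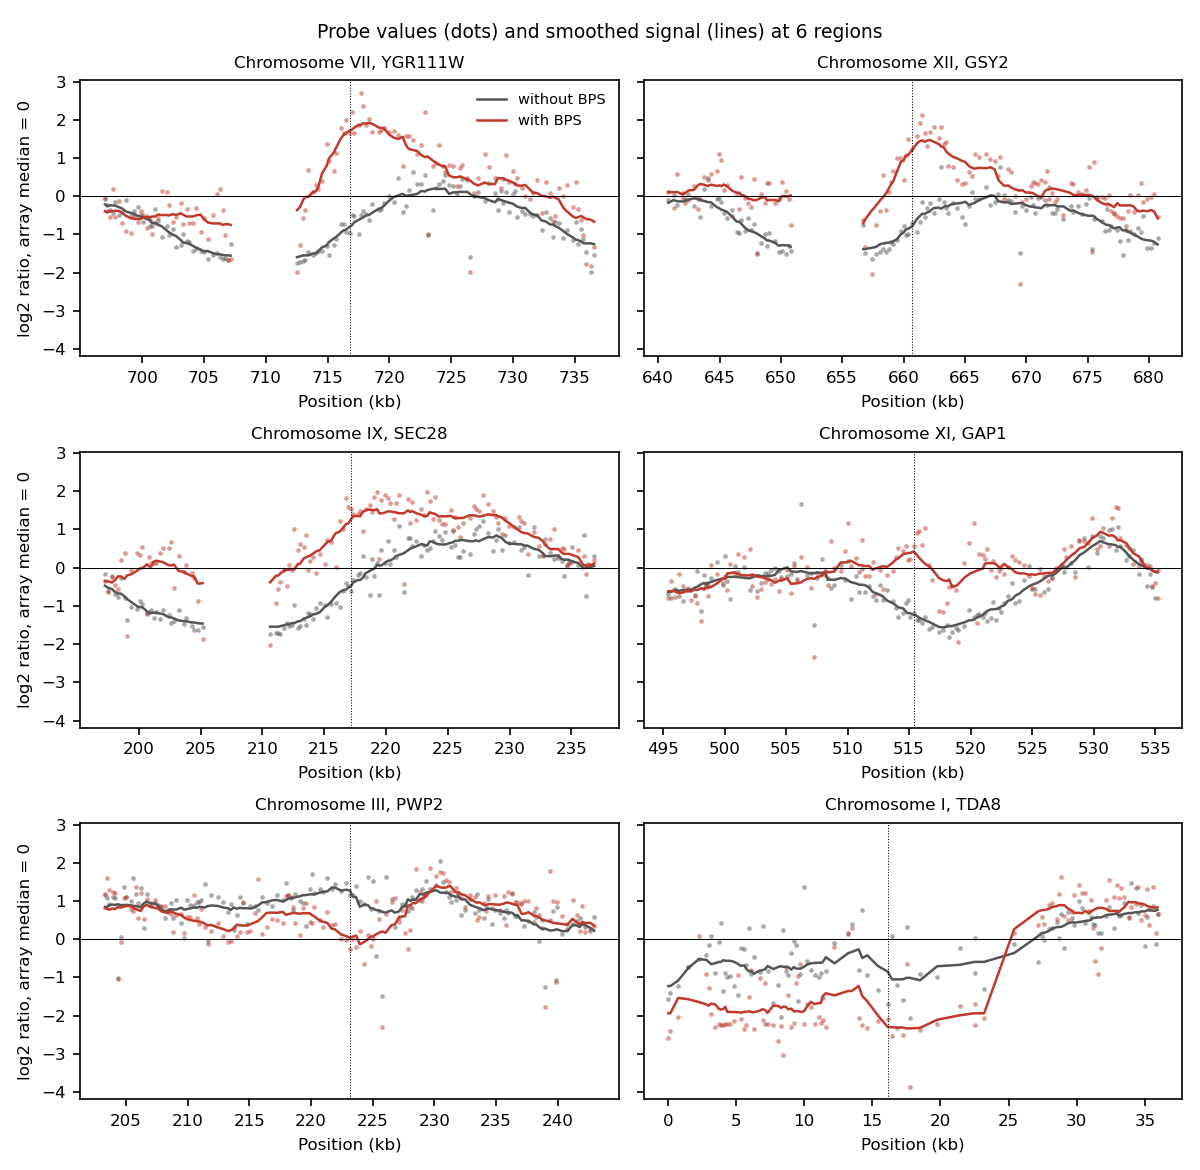
Dots are probes and lines are means within 2 kb (log2 ratio, array median set to 0) against position in kb, in grey without BPS and in red with BPS, at 4 of the largest gains and 2 of the largest losses with dotted lines at their centres. YGR111W had −0.80 without and 1.72 with BPS, PWP2 1.28 and 0.04, and the left end of chromosome I was lower with BPS (−0.85 and −2.30 near TDA8).

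Over the whole genome, 599 probes (1.44%) had a smoothed signal higher by more than 1 log2 unit with BPS and 73 (0.176%) had one lower by as much. At 0.5 log2 units the counts were 3252 and 2063. With chromosome ends, 23 Ty frames and ribosomal DNA left out, 556 and 18 probes passed 1 log2 unit. Those frames miss other Ty elements, and with probes within 1 kb of any probe-free gap over 4 kb left out as well, the counts were 537 and 16. Gains beside such gaps reached further than 1 kb, as on VII (712.8 to 721.3 kb) and XII (657.7 to 665.3 kb). Most of their probes therefore stayed in these counts, which do not show how much the gaps' surroundings contribute. Tracks made from odd-numbered and from even-numbered probes correlated at 0.839 for the difference between the arrays. That correlation describes noise between probes, not between cultures.

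Early-firing origins, where forks first meet hydroxyurea, had a lower median signal with BPS. Over 9 such origins the median was 0.56 without and 0.31 with BPS, at the 97.1st and 85.0th percentiles of 10000 rotations of the list along the genome, as a description of these arrays. The difference had a median of −0.21 (8.06th percentile), with 7 origins lower and 2 higher with BPS. Without BPS 8 of the 9 lay above the genome median, ARS310 being the exception. However, 6 of the 9 are on III and 2 on VI, the chromosomes with the highest medians. Against the median of its own chromosome 8 origins were above it without and 4 with BPS, and of those on III 5 and 1, with a median difference of −0.16 after subtraction of the chromosome medians. ARS315 on III, close to PWP2, had 0.85 ± 0.22 without and 0.06 ± 0.21 with BPS, the most negative difference of the list at −0.79 ± 0.24. ARS416, the ARS1 origin beside TRP1, had 0.77 and 0.35, and ARS306 had 0.52 and 0.10. Smaller differences were seen at ARS307 (−0.25), ARS305 (−0.21), ARS607 (−0.14) and ARS606 (−0.12). ARS309 (1.05 and 1.09) and ARS310 (−0.51 and 0.09) were higher with BPS. Within 1 kb of the origins the median difference was −0.38, and within 5 kb it was −0.15.

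Late or dormant origins were as high and not lower with BPS. Their median over 6 positions was 0.62 without and 0.75 with BPS (96.4th and 98.4th percentiles), and 5 of the 6 were higher with BPS, with a median difference of 0.13 (84.3rd percentile). Its bootstrap interval ran from −0.08 to 0.27. The median difference was 0.03 after quantile normalization, 0.08 (in robust SDs) after scaling and 0.24 within 1 kb. ARS603 on VI had the highest signal of all origins listed, 1.21 ± 0.16 and 1.37 ± 0.11. ARS522 on V differed by 0.26 ± 0.11, the silenced origins at HML by 0.28 ± 0.14, ARS609 by 0.09 and those at HMR by 0.06. ARS304, at 0.96 and 0.75, was the exception. Of the 6, 3 are on III and 2 on VI. Against the median of its own chromosome 4 were above it without and 5 with BPS, and of those on III 1 and 2, with medians of 0.49 and 0.47 after subtraction. Origin positions were placed to about 0.5 kb from general knowledge or by a neighbouring gene, which limits these values to the width of their windows.

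Centromeres, which replicate early, lay in hills of signal on both arrays. The 16 centromeres had medians of 0.53 without and 0.40 with BPS (98.8th and 95.5th percentiles). With distance the median went from 0.58 and 0.49 within 5 kb to 0.56 and 0.46 at 5 to 20 kb, and to −0.08 and 0.02 at 30 to 50 kb. No common shift was seen with BPS: 8 centromeres were higher and 8 lower. CEN5 (0.65 and 1.15), CEN3 (0.87 and 1.35) and CEN13 (1.04 and 1.34) were among the higher, and CEN15 (0.10 and −0.35) and CEN11 (0.78 and 0.33) among the lower. The median difference of 0.002 turned to −0.03 after scaling or quantile normalization, to −0.05 within 1 kb and to −0.02 within 5 kb.

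The outer part of the chromosomes had a median below the genome median without BPS and above it with BPS. The outer 20 kb had a median of −0.13 without and 0.25 with BPS over 30 ends with probes (10.7th and 92.5th percentiles), and 25 of the 30 were higher with BPS, with a median difference of 0.26 at the 99.92nd percentile of rotations. Among the ends higher with BPS, the left end of VIII had the largest difference, from −0.52 ± 0.04 to 0.26 ± 0.10 over 54 probes. The left ends of XI (−0.42 and 0.31), V (−0.11 and 0.61) and XII (−0.70 and −0.03) followed. The 5 ends lower with BPS were the left end of I (−1.11 ± 0.12) and the right ends of I (−0.38), XII (−0.24), X (−0.08) and VIII (−0.06). By distance, the outermost 2.5 kb had medians of −0.84 and −0.70, with a median difference over probes of 0.05. The next 2.5 kb had −0.66 and −0.18, the span from 10 to 20 kb had 0.09 and 0.47, and at 20 to 30 kb the arrays were alike at 0.31 and 0.32.

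Genes for transfer RNAs, short genes transcribed by RNA polymerase III at which replication forks pause, mostly sat in narrow dips of signal, with a lower median with BPS. Within 0.5 kb of a tRNA gene the median over probes was −0.11 without and −0.38 with BPS. At 1 to 2 kb it was 0.03 and 0.31, so the flanks stood higher with BPS while the genes stood lower. Over 275 tRNA genes the list median was −0.12 without and −0.34 with BPS, with 185 genes lower and 90 higher with BPS and a median difference of −0.17. All 10000 rotations of the list gave a higher median difference than this. The mean within 0.5 kb minus the mean from 1 to 3 kb had a median of −0.10 without and −0.49 with BPS. It was negative, a dip, at 186 of the 275 genes without and 246 with BPS, and it was lower with BPS at 247. This contrast was chosen after the values were seen.

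**Figure D3:**
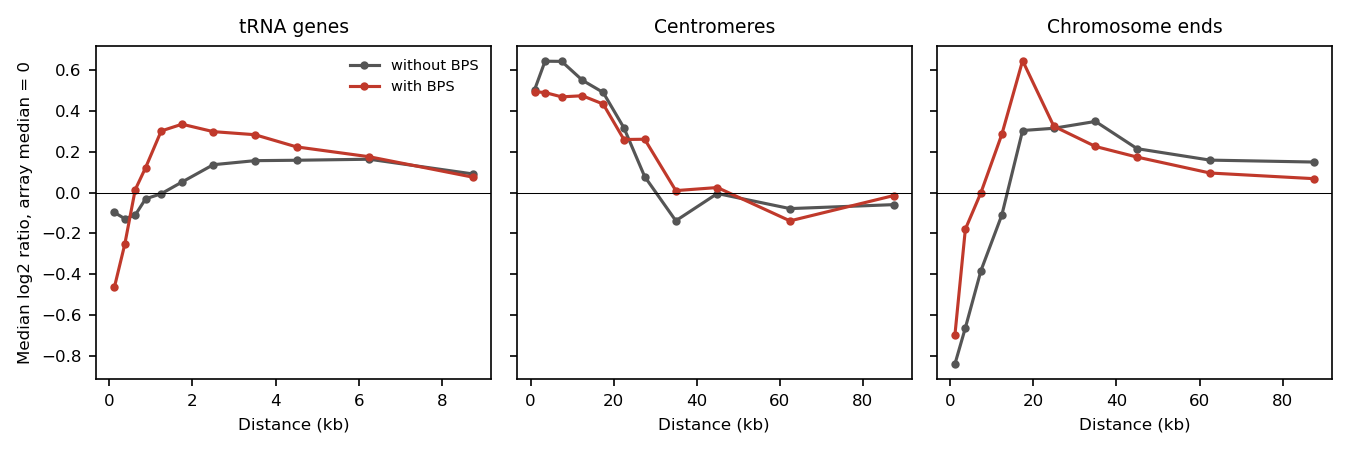
Points are medians over probes (log2 ratio, array median set to 0) in bins of distance in kb from the nearest tRNA gene, centromere or chromosome end, in grey without BPS and in red with BPS. The dip at tRNA genes is deeper with BPS (−0.46 against −0.10 within 0.25 kb, and −0.25 against −0.13 at 0.25 to 0.5 kb). The centromere profiles are close, and the outer 20 kb of chromosomes are higher with BPS except for the outermost 2.5 kb, where the median difference is 0.05.

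The lists of genes were chosen for the treatments and describe where the signal lay, not how much the genes were transcribed. Genes of the iron regulon, which iron shortage induces, had list medians of 0.33 without and 0.53 with BPS, with quartiles of −0.34 and 0.66 without BPS. Of 26 measured genes 17 were higher and 9 lower with BPS. The median difference of 0.19 lay at the 97.6th percentile of 10000 random lists matched on mean signal, and its bootstrap interval over genes, −0.04 to 0.31, included 0. ARN2, a siderophore transporter gene near the left end of VIII, had −0.45 ± 0.04 without and 1.21 ± 0.08 with BPS. TIS11, which directs decay of messages for iron-using proteins (0.39 and 1.35), the ferric reductase gene FRE2 (−0.23 and 0.57) and the vacuolar iron transporter gene FTH1 (0.61 and 1.32) were also higher. FRE1, encoding another ferric reductase, had −0.34 and −1.02, and FET3, the multicopper oxidase of iron uptake, had −0.69 and −0.63. Without the genes in the outer 20 kb of chromosomes the median difference was 0.07 over 21 genes, and it was 0.007 when positions were moved 1 kb along the chromosomes and 0.15 when they were moved 1 kb the other way.

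Glycolytic, small nucleolar RNA and ribosomal protein genes had lower medians with BPS. Among 12 glycolytic genes, 9 were lower, with list medians of 0.55 and 0.07 and a median difference of −0.42 at the 0.01st percentile of matched lists. The glyceraldehyde-3-phosphate dehydrogenase genes TDH3 (−0.04 and −0.72) and TDH2 (0.59 and −0.08), the phosphoglycerate mutase gene GPM1 (−0.16 and −0.77) and the alcohol dehydrogenase gene ADH1 (0.50 and 0.02) were lower, and the enolase gene ENO2 (1.17 and 1.62) and PGK1 (0.85 and 1.01) were higher. Moved by 1 kb the glycolytic positions gave 0.14, and moved the other way they gave −0.31. Of 38 genes for small nucleolar RNAs with a probe, 28 were lower with BPS and the median difference was −0.34, below all 10000 matched lists and at the 0.62nd percentile of rotations. It was −0.10 with positions moved by 1 kb and −0.16 the other way, and 33 of the 38 genes rested on 1 probe each. SNR85 had −0.28 and −1.37, and SNR77 had 0.01 and 0.86. Ribosomal protein genes differed less, with 74 of 125 lower and a median difference of −0.10 (1.09th percentile of matched lists and 8.43rd of rotations), from −0.93 at RPS21B to 1.34 at RPS25B.

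Of the 10 genes for ribonucleotide reductase, the target of hydroxyurea, and for the DNA damage response, 9 were lower with BPS, with a median difference of −0.21 (11.1th percentile). HUG1 (0.09 and −0.82, 1 probe) was lowest and RNR2 (−0.35 and 0.10) was the 1 that was higher. Histone genes had medians of 0.38 and −0.19 over 7 genes, 6 of them with 1 probe each. Their median difference was −0.30 (5.59th percentile of matched lists and 12.4th of rotations), which was 0.11 with positions moved by 1 kb and −0.56 the other way. HTA2 had 0.54 and −0.26, and HHF2 had 0.38 and 0.68. The pheromone-induced genes, which alpha factor switches on in the G1 cells, had a median difference of −0.06 with 8 of 19 higher. BAR1, the protease that degrades alpha factor, had −1.05 and −0.10, and FUS1, required for cell fusion, had 0.45 and −0.55. Among 73 reading frames of at least 5 kb the median difference was −0.05, which became 0.01 after quantile normalization, with SNF2 at 1.13 ± 0.15 and NUP192 at −0.53 ± 0.18.

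**Figure D4:**
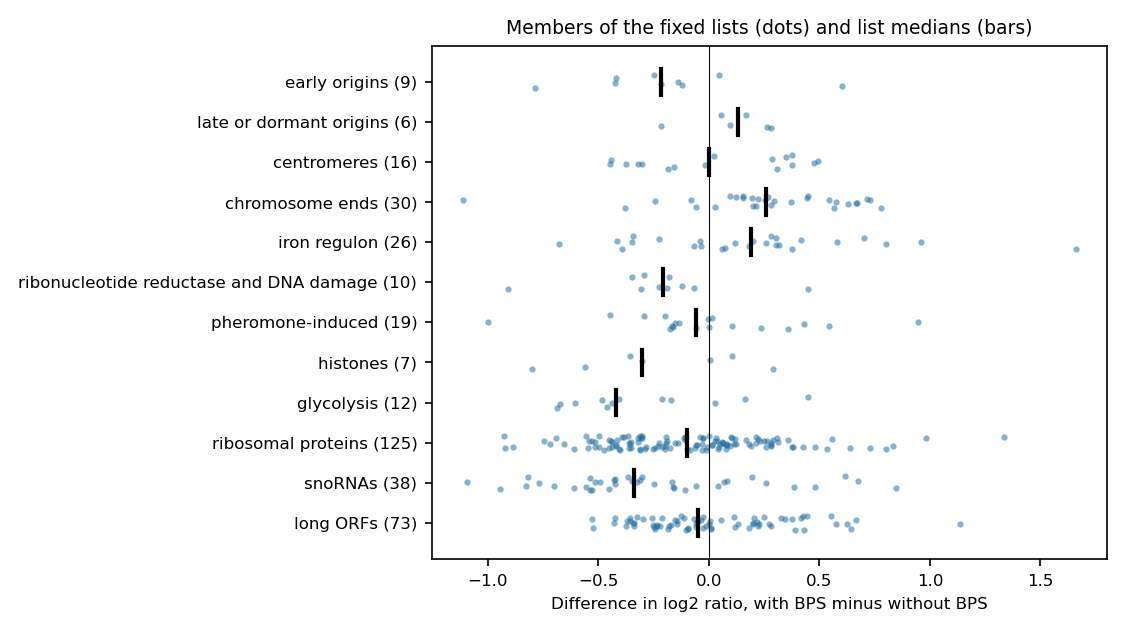
Each dot is a member of a fixed list (number measured in brackets), placed by its difference in log2 ratio with BPS minus without BPS, and each bar is the list median. Chromosome ends have a median of 0.26, the iron regulon 0.19, glycolytic genes −0.42 and small nucleolar RNA genes −0.34.

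Among chromosomes the medians of the arrays lay close together. Between the first and last ribosomal RNA genes on XII lay 7 probes, with a median of 0.74 without and 0.28 with BPS. None of the 7 was higher with BPS. Not all of them lie in the tandem repeats. Those at 476.0 and 481.9 kb bordered a gap that holds a Ty frame, with a mean of −0.44 without and −0.97 with BPS. A probe within the repeats averages over many copies, but the 7 values do not describe the repeats alone.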

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

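The differences in this part were not tested, since there was 1 array per group, and all of the tests of explanations were chosen after the result was seen. Each place or list below lay on opposite sides of the genome median in the 2 recoveries. Places below the median without BPS and above it with BPS were YGR111W (difference 2.52) and SHY1 (2.41) in 1 block on VII, GSY2 on XII (2.0), SEC28 on IX (1.74), KTD1 on I (1.73), RRN6 on II (1.69), YPS7 (1.66), ATP22 (1.58) and GCN2 (1.59) on IV, GAP1 on XI (1.66) and SNZ3 on VI (1.53). Among origins ARS310 crossed in the same direction (0.60), and among lists the chromosome ends did (0.26). Histone genes (−0.30) and small nucleolar RNA genes (−0.34) crossed from above to below the median.

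The 10 largest gains with BPS could come from noise of single probes, from the wider scale of the array with BPS, or from the treatment. Noise is argued against for gains on several probes: when the 10 largest gains were chosen on odd-numbered probes, the even-numbered probes at those places gave a median of 1.63, with a range of 1.19 to 2.36. SNZ3, on 1 probe, cannot be checked this way. A wider scale is argued against too, because the median at the gains was still 1.63 (1.47 to 2.43) after quantile normalization. An effect of the BPS treatment and a chance difference between the 2 cultures cannot be told apart, with 1 array per group. Dye balance, the G1 channel of each array and the authors' normalization stay open as well, since no scanner values were used here. The 3 largest gains bordered probe-free gaps where assembly R64 places transposons. Repeats or insertions particular to WFA73 would be on both arrays and in the G1 DNA, so alone they would not give a difference. Whether they influence where gains lie stays open.

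The deeper dip at tRNA genes with BPS could reflect repeated sequence near full Ty elements, which insert beside tRNA genes, a property of intergenic probes, the wider scale, or the treatment. Repeats near full Ty elements of the array design are argued against as the whole cause, as 219 tRNA genes more than 5 kb from 23 Ty frames and from every probe-free gap over 4 kb gave a median change of the dip of −0.34 (95% bootstrap interval −0.42 to −0.29). Intergenic probes in general are argued against as the whole cause, as those within 0.5 kb of a tRNA gene differed by −0.16 (−0.20 to −0.11) from those more than 5 kb away. A wider spread of values is argued against as the whole cause by a change of −0.32 (−0.35 to −0.26) after quantile normalization. That method does not equalise the contrast of narrow features. With limits at 3 noise SDs of each array, narrow minima numbered 27 without and 102 with BPS, and narrow maxima 8 and 44. A stronger contrast of narrow features in general was not tested as the cause of the dip and stays open. Places lower than their flanks by over 1 log2 unit numbered 35 without and 199 with BPS, and similar shares, 25.7% and 28.1%, lay near tRNA genes. The BPS treatment and chance between cultures cannot be told apart with 1 array per group, and the G1 channel of each array stays open. Base composition, short terminal repeats near tRNA genes and Ty insertions particular to WFA73 would be the same on both arrays. Alone they would not give a difference, but whether they influence its size stays open because no sequence was used here.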

How the results depend on the processing

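Alternatives at 1 and 1.5 robust SDs were added after the data were seen, as were all those for shared maxima, heights at maxima and single regions. The moved gene positions, the removal of chromosome ends from gene lists and the removal of probe-free gaps were also added then. With no replicates no direction was called, but the sign of a median turned for joint maxima, histones and glycolysis in the settings given here, for centromeres under scalings and windows and long reading frames under a scaling given with them, and for pheromone-induced genes moved by 1 kb (0.04). The median of chromosome I with BPS turned as well, from −0.09 with all probes to 0.04 with ends left out. The 20 regions with the largest differences kept their sign in 80 of 80 alternatives of window and scaling. They were chosen as extremes of the same difference, so a kept sign was nearly fixed in advance and is no support. At YRF1-4 and YLL066W-B, on 1 probe each, windows of 1, 2 and 4 kb gave the same value. A half-width of 4 kb left less at many, such as −0.05 at FLO5, −0.59 at FLO1, −0.41 at YRF1-6, −0.73 at PWP2, 0.58 at SNZ3 and 1.06 at RRN6. The sign turned at 7 of the 10 highest sites without BPS after quantile normalization, 4 after scaling and 1 with a half-width of 4 kb, and at 1 of the 10 highest with BPS after quantile normalization. The cause was not tested for the values that follow. Averaging within 2 kb moved the correlation to 0.865 and the slope to 1.15. Peaks at 2 robust SDs numbered 4 without and 38 with BPS, and 0 at 3 or 4 robust SDs. At 1.5 robust SDs there were 93 and 173 maxima. The share of maxima without BPS found with BPS was 71.0% at 1.5 robust SDs, 50% at 2 robust SDs, 59.9% with a half-width of 4 kb and 58.9% within 1 kb, and the converse share was 38.2%, 5.26%, 57.4% and 52%. The median difference at joint maxima was 0.28 at 1.5 and 0.29 at 2 robust SDs, 0.19 with a half-width of 4 kb, 0.19 after scaling (in robust SDs) and −0.00098 after quantile normalization. Early origins had −0.38 within 1 kb. Gene positions moved by 1 kb gave 0.0069 for the iron regulon, −0.32 for ribonucleotide reductase and DNA damage, 0.11 for histones, 0.14 for glycolysis and −0.10 for small nucleolar RNAs (−0.16 the other way). In the gene lists 42 values stayed within their spread and the 6 given here did not, for single regions 110 stayed and 50 did not, and by chromosome 32 of 32 stayed. The 110 include the falls at SNZ3 and FLO5 with a half-width of 4 kb, as 1 or 2 probes give no narrow spread. The 32 include the turn of sign on chromosome I. Lists of all origins and of Ty elements were not run. No paired analysis was possible because each group had 1 array. Signal over background was not assessed, as no intensities were used here.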

Other observations

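The values in this part were all chosen after the data were seen and carry no test. Of the 10 lowest smoothed points without BPS, 6 stayed below −1 with BPS and 4 did not. Points within 20 kb of chromosome ends, within 1 kb of 23 Ty frames or of ribosomal DNA, or with fewer than 8 probes in the window were left out of this search, but points beside other Ty elements were not. Points had to lie at least 10 kb apart, which left out a neighbour of the first at 707.2 kb on VII (−1.56 and −0.75). The 4 were those at the edge of YGR109W-B on VII (712.5 kb, −1.59 without and −0.36 with BPS), downstream of GAP1 on XI (517.8 kb, −1.56 and −0.33), at AIR1 on IX (211.1 kb, −1.55 and −0.21) and on XII at 656.9 kb (−1.38 and −0.60). Within the same limits the lowest points with BPS were near FLO1 on I (−0.50 without and −1.74 with BPS), at YLR278C on XII (−1.11 and −1.61) and at YOR343C on XV (−1.36 and −1.61). Lower values with BPS lay outside these limits, such as −2.51 on XII (11.4 kb, 1 probe) and −2.34 at FLO5 on VIII (2 probes).

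The 3 largest gains bordered long stretches without probes, where assembly R64 places transposons. There were 53 gaps of more than 4 kb between probes away from chromosome ends. In the 5 kb on either side of a gap the median signal was −0.26 without and −0.0004 with BPS, and the median difference over gaps was 0.07 (interquartile range −0.19 to 0.35), higher with BPS at 30 and lower at 23. The gaps at YGR109W-B on VII (1.36 ± 0.15 SE over 39 probes), at YIL082W-A on IX (1.34 ± 0.09) and at HAP1 on XII (1.27 ± 0.12) ranked 1, 2 and 3 of 53 by difference, and the next had 0.76. They were also the 3 lowest without BPS, at −1.30, −1.35 and −1.07. YGR109W-B and YIL082W-A are reading frames of Ty3 elements, and HAP1, a regulator that responds to haem, carries a Ty1 element in the reference strain. Whether WFA73 carries these insertions was not analysed here.

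The left end of chromosome I stood apart from the other ends as a block with a sharp edge. Over the 65 probes in the first 24 kb the median was −0.85 without and −2.15 with BPS, and 57 probes were lower with BPS. Over the 91 probes from 24 to 48 kb the medians were 0.69 and 0.76.

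Narrow features were counted on both arrays. Places where the mean within 0.5 kb exceeded its flanks, at 1.5 to 3 kb, by more than 1 log2 unit numbered 14 without and 138 with BPS, against means of 2.7 and 25.9 when the residuals of probes were shuffled 20 times. Places lower than their flanks by as much numbered 35 and 199, against 15.8 and 86.8. A fixed limit favours the array with the wider spread, and the observed counts were 5.19 and 5.33 times the shuffled ones for maxima and 2.22 and 2.29 times for minima. With the limit set at 3 noise SDs of each array there were 8 and 44 maxima, against shuffled means of 2.2 and 4.05, and 27 and 102 minima, against 11 and 27.7. Those are 3.64 and 10.9 times the shuffled counts for maxima and 2.45 and 3.68 times for minima. Of the minima at the fixed limit 25.7% without and 28.1% with BPS lay within 0.5 kb of a tRNA gene, where 2.36% of probes lie. At PSH1, which encodes a ubiquitin ligase for the centromeric histone, on XV (229.6 kb), the ratio within 0.5 kb was 1.75 without and 6.18 with BPS, and at RRN6 on II (200.1 kb) it was 1.10 and 3.84. BFR1 on XV (719.8 kb) went the other way, with 1.92 and 0.623.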
